A study of Mus musculus with 12 samples.

How the data were processed

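RNA of 12 mouse liver libraries was measured by high-throughput sequencing, 4 libraries for each of the labels CTL, DM and DMH. The labels do not spell out DM or DMH, so both names are used here as given. The title of the series concerns an anti-diabetic effect in liver of a red form of the green alga Chlamydomonas reinhardtii that holds much protoporphyrin IX, the porphyrin from which haem is made. The labels do not say which groups received it. The source labels name liver, while the extraction text of the labels mentions retinas; levels of liver and retina genes were therefore checked. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

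Per the series' design text, base-called reads were checked with FastQC 0.11.8, filtered with Trimmomatic 0.36, aligned to GRCm38 with HISAT2 2.1.0 and counted per gene with StringTie. The authors deposited a whole-number read count for each of 54838 Ensembl genes in each library, which is the unit of every test below unless another is named. StringTie derives gene counts from the coverage of assembled or annotated transcripts, so a count of a gene with overlapping neighbours or near-identical copies depends on how shared coverage was divided. The version of StringTie, the annotation release and the strand setting are not given in the sources used here. The values of genes that share exonic bases with another gene are therefore uncertain. Beside those marked at their mention, these are Abcb11, Alas1, Clcn4, Cox5a, Ctsd, Fgg, Gk, Gria3, Hspa1a, Lipe, Mlxipl, Ndufb8, Psma5, Rpl6, Rpph1, Rps2, Rps3, Slco2a1 and Tef, whose overlapping partners averaged at most 1.8 CPM each. Genes with near-identical copies are uncertain too. The deposited FPKM of each gene stands beside its count; the design text names TMM normalisation before FPKM, but the deposited values equal the count divided by 1 fixed length per gene and by the plain library total. The submitters' processing notes also list DESeq2, with neither version nor role. The design text names p-values adjusted for the false discovery rate and counts a gene as changed at a fold change of at least 2 with p under 0.05. This fold 2 rule was applied here with unadjusted p, so it may be looser than the rule of the submitters. The pathway analyses of the design text with clusterProfiler and DAVID were not used here.

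Library totals ran from 13430122 to 17038017 counts. Within groups, replicate pairs differed by a chi-square of 39.5 to 432 per degree of freedom over genes with at least 20 counts in the pair, so no library was a copy of another, and all 12 were used. Coordinates are those of the deposited table on GRCm38; 54809 of the 54838 identifiers were found in the GENCODE M21 annotation, 54123 of them with the same start and end. Shared sequence was measured on GENCODE transcripts, for some of the named genes only, as the percentage of 25-base words of a gene found in another. Processed pseudogenes, of which ribosomal protein genes have many, were not searched.

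Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests with robust dispersion and TMM factors. All 12 libraries entered 1 model with a mean per group, which left 9 residual degrees of freedom. Genes were kept when filterByExpr passed them at a minimum count of 10 and a minimum total of 15, which left 14643 genes. The 3 comparisons were DM against CTL, DMH against DM and DMH against CTL. Adjusted p-values are Benjamini-Hochberg values over all tested genes of a comparison, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values, written with their standard error (SE); standard errors were taken from the fold change and the F statistic. Levels are counts scaled to a common library total (CPM) with TMM factors, given as mean ± SD over 4 libraries. Levels of the liver and retina genes, and of overlapping genes set beside each other, are CPM of the plain library total without TMM factors. Log2 levels used a prior count of 2.

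Gene lists of liver pathways and of the cell types a piece of liver can hold, 57 in all, were written from textbook knowledge. The 54 with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Their p-values were adjusted over the 54 lists of a comparison. Camera compares a list with all other tested genes. A list is said to be higher or lower where its adjusted p was under 0.05 at the preset correlation. No list passed with the estimated correlation in any comparison. Where genes are said to pass adjusted over the list alone, their edgeR p-values were adjusted within that list. Such counts are not corrected for the 54 lists examined, and genes of a list may be correlated.

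Genes were named by a rule. It takes, among called genes whose groups do not overlap and whose mean over the 8 libraries is at least 5 CPM, the 6 with the largest rise and the 6 with the largest fall, leaving out symbols of unnamed models. It adds up to 3 called members of each of the 8 lists of smallest camera p, a set of 12 metabolic and haem genes, of which 11 are reported here, and up to 8 genes called in both DM against CTL and DMH against DM. All other named genes were chosen after their values were seen and are marked as such at their mention.

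The comparisons, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except 3 alternatives added later: leaving out mitochondrial genes together with the mitochondrial pseudogenes of chromosome 1, removing a trend with gene length, and adding the mitochondrial percentage of each library as a covariate. The alternatives fixed beforehand were RLE size factors, DESeq2 1.42.0, limma on log2(FPKM + 1) for genes of at least 1 FPKM in 4 libraries, no filter on low counts beyond a total of 1, a strict filter of at least 50 counts in 4 libraries, fits of the 8 libraries of each pair alone, a replicate number as a block, each library left out in turn, and the fold 2 rule of the design text. Fold changes on the log2(FPKM + 1) scale understate the change of low genes. Overlaps between comparisons that share libraries were set beside 30 simulations of unchanged groups, drawn from the fitted means and dispersions over 14643 genes. Single values of the 12 libraries were compared with two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

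The test was checked on counts drawn from the means, dispersions and library sizes of these data over 14643 genes, with 200 genes changed in each comparison. At 2-fold, edgeR recovered 9 of 100 changed genes for DM against CTL, 11 for DMH against DM and 10 for DMH against CTL. At 4-fold it recovered 60, 62 and 72 of 100. False calls numbered 5, 5 and 2 for edgeR and 23, 22 and 34 for DESeq2. Camera recovered a list of 20 genes raised 2-fold in all 3 comparisons with 0 false lists. The genes were drawn independently of each other, so this cannot show how many false lists camera gives where genes are correlated. At this depth and replication a change of 2-fold was therefore often not detectable in single genes.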

Results

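Gene expression was measured in 12 libraries of mouse liver, 4 for each of the groups CTL, DM and DMH, at 13430122 to 17038017 counted reads per library. CTL libraries held 15512699 to 16321134 counts, DM libraries 13430122 to 17038017 and DMH libraries 14376021 to 16631264. Liver genes were abundant in all libraries: albumin (Alb) lay between 13500 and 37100 CPM and apolipoprotein A1 (Apoa1) between 6750 and 14500. Retina genes were examined because of the extraction text. The photoreceptor gene Sag did not exceed 0.447 CPM in any library, Prph2 and Crx were at 0 counts in all 12, and Gnat1 reached 2.88 to 54.1 CPM.

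Genes of the mitochondrial genome took 15.4% ± 7.37 of the counts in CTL, 24.2% ± 6.55 in DM and 30.1% ± 6.22 in DMH (SD, n = 4 each). The share was lowest in CTL1 at 7.88% and highest in DMH1 at 37.6%, and the groups overlapped. Exact permutation tests over 70 arrangements gave p = 0.2 for DM against CTL, 0.257 for DMH against DM and 0.0571 for DMH against CTL, or 0.257, 0.257 and 0.171 after adjustment over the 3 tests. Pseudogene copies of mitochondrial genes on chromosome 1 took a further 4.27% to 18.4% of the counts per library. Of the 25-base words of these 7 copies, 97.2% to 100% occur in genes of the mitochondrial genome, so the values of both are uncertain. The leading principal component of the log2 CPM values held 23.5% of the variance and the next 15.7%.

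**Figure D1:**
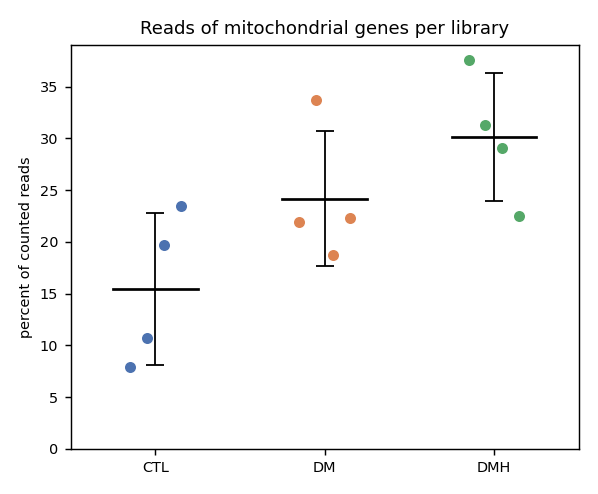
Percentage of counted reads assigned to genes of the mitochondrial genome in each of the 12 libraries, by group; points are libraries, lines are group means and bars are SD (n = 4). CTL libraries range from 7.88% to 23.5%, DM libraries from 18.7% to 33.7% and DMH libraries from 22.5% to 37.6%.

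The comparison of DM with CTL asked how the liver of the DM group differed from that of CTL. Hsd3b2, a 3-beta-hydroxysteroid dehydrogenase of steroid metabolism (ENSMUSG00000063730, chromosome 3, 98709255 to 98724543), rose by 2.61 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 0.0153). Its level went from 9.39 ± 4.89 to 57.5 ± 8.12 CPM (SD, n = 4 each). Cplane1, a gene needed to build cilia (ENSMUSG00000039801, chromosome 15, 8169106 to 8271158), rose by 2.54 ± 0.34 (adjusted p = 0.0125). The vesicular glutamate transporter gene Slc17a8 (ENSMUSG00000019935, chromosome 10, 89574020 to 89621253) rose by 2.02 ± 0.32. The potassium-chloride cotransporter gene Slc12a7 (ENSMUSG00000017756, chromosome 13, 73733094 to 73816754) rose by 1.72 ± 0.28 and the succinate receptor gene Sucnr1 (ENSMUSG00000027762, chromosome 3, 60081869 to 60087566) by 1.71 ± 0.27. Dhx15, which encodes a splicing helicase (ENSMUSG00000029169, chromosome 5, 52150203 to 52190514), rose by 1.47 ± 0.26. Igkc, the constant region of the immunoglobulin kappa chain (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), changed by -2.84 ± 0.50, from 145 ± 12.9 to 20.3 ± 18.9 CPM (adjusted p = 0.0467). Of the further falls, the serine dehydratase-like gene Sdsl (ENSMUSG00000029596, chromosome 5, 120458186 to 120472810) changed by -2.25 ± 0.30 and the secreted protease inhibitor family gene Wfdc2 (ENSMUSG00000017723, chromosome 2, 164562413 to 164568510) by -2.13 ± 0.35. The inhibitory leukocyte receptor gene Pirb (ENSMUSG00000058818, chromosome 7, 3711409 to 3720391) changed by -1.70 ± 0.30 and the prostaglandin transporter gene Slco2a1 (ENSMUSG00000032548, chromosome 9, 102988712 to 103096002) by -0.97 ± 0.16. Exons of Hsd3b2 overlap Zfp697 on the other strand, which averaged 1.9 CPM, and 16.6% of its 25-base words occur in Hsd3b3.

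In all, 22 genes were higher and 10 lower in DM than in CTL, of 14643 tested, and 2758 reached an unadjusted p under 0.05. Of the 22 and 10, 17 and 7 are protein-coding and 19 and 9 changed at least 2-fold. On log2(FPKM + 1) with limma the split was 16 higher and 63 lower, with the median of all genes shifted to -0.115. DESeq2 called 387 higher and 483 lower, and fold 2 with unadjusted p under 0.05 gave 418 and 736. The fit of these 8 libraries alone called 189 and 178, and edgeR without a filter 40 and 25. With the mitochondrial percentage as a covariate, an alternative chosen after seeing the data, edgeR called 1 and 2, and 3 of the 15 named genes called here kept their calls. The count of 32 was 21 without CTL1, 13 without CTL2, 7 without CTL3, 16 without CTL4, 20 without DM1, 7 without DM2, 7 without DM4, 59 without DMH1, 12 without DMH2, 248 without DMH3 and 80 without DMH4. Of the genes named above, Cplane1 lost its call without CTL3 (adjusted p = 0.0524), Sdsl without DM2 or DM4 (up to 0.0601) and Hsd3b2 without CTL3, DM2 or DM4 (up to 0.0672). The other 8 each lost theirs without CTL2, CTL3, DM1, DM2, DM4 or DMH2, and some also without CTL1, CTL4, DM3 or DMH1, with adjusted p up to 0.135.

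Markers of Kupffer cells, the resident macrophages of the liver, lay lower in DM than in CTL for all 12 genes of the list, with a median log2 fold change of -2.13 (camera adjusted p = 1.28e-11; adjusted p = 0.49 with an estimated correlation). None of the 12 was called over all genes, while all 12 passed adjusted over the list alone. Examples chosen after their values were seen are the secreted scavenger gene Cd5l (-2.51 ± 0.56, adjusted p = 0.0733), the macrophage marker Adgre1 (-2.32 ± 0.49, 0.0626) and the Kupffer lectin Clec4f (-1.46 ± 0.35, 0.0869). Without DMH3 the 3 passed (0.0278, 0.0278 and 0.0356). Mean deviations of the list from each gene's mean were 0.644 to 1.61 in the CTL libraries and -1.83 to -0.532 in the DM libraries. Neutrophil markers lay lower for 6 of 6 (median -4.79, camera adjusted p = 5.43e-05, and adjusted p = 0.49 with an estimated correlation). Of them 0 were called over all genes and 6 adjusted over the list alone. The calprotectin subunit S100a8, chosen after its value was seen, stood at -5.17 ± 1.28 (edgeR adjusted p = 0.0937) and at -2.90 without CTL1. The acute phase list, plasma proteins that hepatocytes make in inflammation, lay lower for 19 of 19 (median -2.04, camera adjusted p = 3.43e-09, and adjusted p = 0.587 with an estimated correlation). Of them 0 were called over all genes and 17 adjusted over the list alone. The mean deviation of the list was 3.87 in CTL1, against 0.116 to 0.93 in the other CTL libraries and -0.919 to -0.717 in DM. Saa1 stood at 25740 CPM in CTL1, against 96.6, 174 and 1103 in the other CTL libraries and 28.1 to 34.8 in DM. Without CTL1 the median of the acute phase list was -0.87 (quartiles -1.69 and -0.57), that of the neutrophil markers -2.48 and that of the Kupffer markers -2.08. The mitochondrial share of CTL1 was the lowest of all libraries.

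Genes of the cytosolic ribosome lay lower in DM for 41 of 42 (median -0.49, camera adjusted p = 1.09e-11, and adjusted p = 0.49 with an estimated correlation). Over all genes 0 were called, and 16 adjusted over the list alone. Targets of p53, which respond to DNA damage, were higher as a list (11 of 14, median 0.74, camera adjusted p = 5.43e-05, and adjusted p = 0.36 with an estimated correlation), with 5 higher adjusted over the list alone. Among them cyclin G1 (Ccng1, ENSMUSG00000020326, chromosome 11, 40748552 to 40755311) rose by 1.07 ± 0.18 (adjusted p = 0.041; up to 0.122 without CTL1 to CTL4, DM2 to DM4 or DMH2). The 13 mitochondrially encoded genes of oxidative phosphorylation were higher as a list (12 of 13, median 0.86, camera adjusted p = 0.000168, and adjusted p = 0.622 with an estimated correlation). Of them 0 were called over all genes and 0 adjusted over the list alone, beside the mitochondrial share of DM given above. Bile acid genes were higher as a list (15 of 19, median 0.29, camera adjusted p = 0.00191, and adjusted p = 0.36 with an estimated correlation), with 0 called and 6 adjusted over the list alone. Chosen after their values were seen, the bile acid uptake carrier Slco1b2 stood at 1.03 ± 0.19 (edgeR adjusted p = 0.0563) and the export pump Abcb11 at 1.59 ± 0.43 (0.104). Slco1b2 passed without DM3, DMH1, DMH3 or DMH4 (0.0318 to 0.0491) and Abcb11 without CTL1 (0.0343). Antigen presentation genes were lower as a list (13 of 15, median -0.72, camera adjusted p = 0.00191, and adjusted p = 0.585 with an estimated correlation), with 0 called and 9 adjusted over the list alone. Further lists lower in DM were those of the cell cycle (18 of 20, median -0.59), inflammatory cytokines (14 of 14, -1.02), periportal hepatocytes (10 of 10, -0.83), sinusoidal endothelium (12 of 12, -0.47), heat shock (12 of 14, -0.38), T and NK cells (7 of 8, -0.93) and monocyte-derived macrophages (8 of 10, -0.53). Further lists higher were male-biased liver genes (14 of 19, 0.89) and the circadian clock (13 of 18, 0.25). The camera adjusted p of these 9 lists ran from 0.0016 to 0.0333 and the adjusted p from 0.496 to 0.658 with an estimated correlation. None of their genes was called over all genes. Adjusted over the list alone, 3 periportal, 2 male-biased, 1 T and NK cell, 1 macrophage and 1 clock gene passed. Of the 54 lists tested, 5 were thus higher and 12 lower in DM. The heat shock list lost its call without CTL3 (camera adjusted p = 0.108) or DM4 (0.0529), and the clock list without CTL2 (0.103) or DM1 (0.102). The calls of T and NK cells ended without CTL4 (0.0972) or DM4 (0.0569), of endothelium without CTL2 (0.0599), CTL3 (0.0773) or DM4 (0.0928), and of monocyte-derived macrophages without CTL3 (0.0501), DM1 (0.0516) or DM4 (0.0928). With the mitochondrial percentage as a covariate the calls of endothelium (0.249) and monocyte-derived macrophages (0.0878) ended. That of the mitochondrially encoded genes ended too (0.469), by construction, as these genes are counted in that percentage. With a length trend removed, also chosen after seeing the data, those of the clock (0.0601) and of T and NK cells (0.0609) ended. The mean deviation of the male-biased list was -2.49 in CTL1, -0.423 to 0.145 in the other CTL libraries and -0.148 to 0.613 in DM, and its call held without CTL1. The median of the periportal list was -0.286 without CTL1, that of heat shock -0.645 without DM1 and that of the mitochondrially encoded genes 0.456 without DM2.

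**Figure D2:**
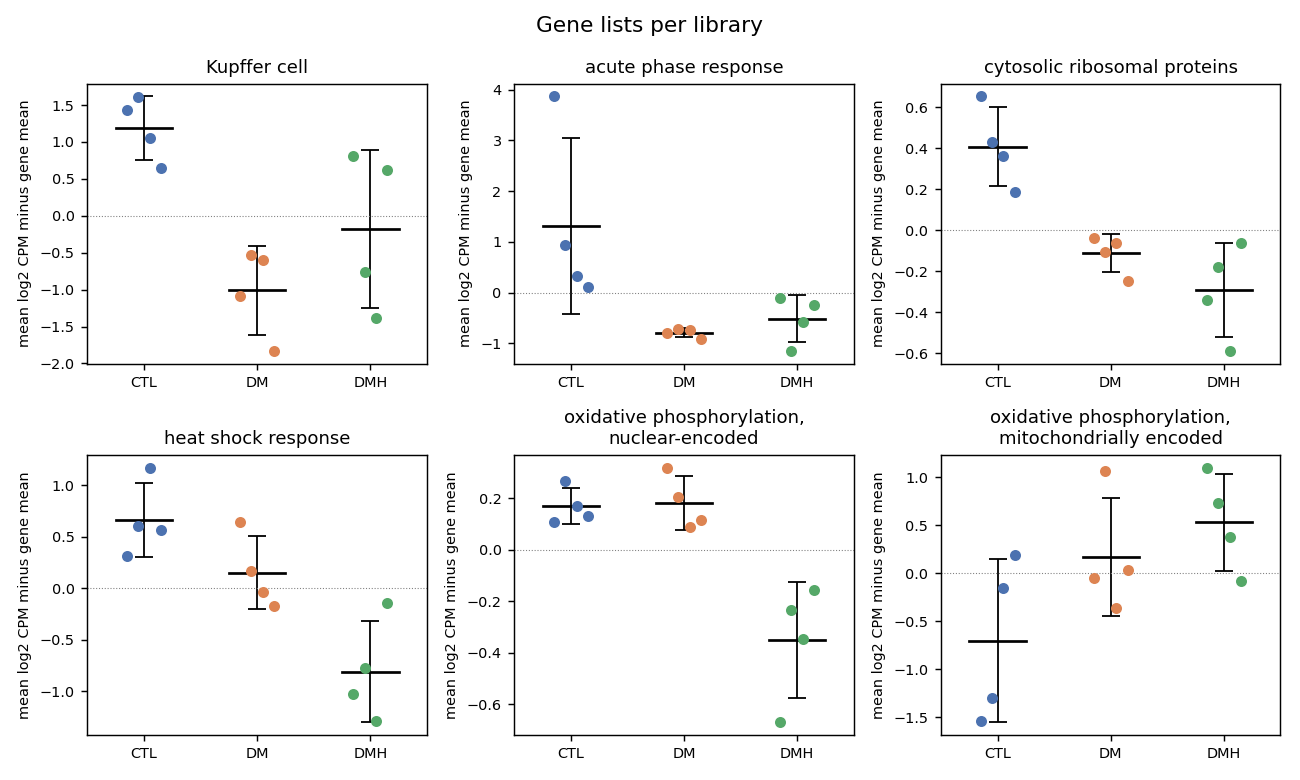
Mean over the genes of each of 6 lists of log2 CPM minus the gene's mean over all 12 libraries, by group; points are libraries, lines are group means and bars are SD (n = 4). Kupffer markers lie at 0.644 to 1.61 in CTL and at -1.83 to -0.532 in DM, and the acute phase list stands at 3.87 in CTL1.

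The 11 reported genes of glucose, lipid, bile acid and haem metabolism chosen beforehand had an edgeR adjusted p of 0.104 or more in DM against CTL. The gluconeogenic genes Pck1 and G6pc gave 0.08 ± 0.31 and 0.79 ± 0.40. The sign of Pck1 turned to -0.04 on log2(FPKM + 1). Lipid genes went both ways: Srebf1, the regulator of fat synthesis, 1.59 ± 0.43 (adjusted p = 0.104), Fasn 0.49 ± 0.48, Scd1 -0.94 ± 0.59 and Cpt1a, which admits fatty acids to mitochondria, -0.39 ± 0.18. The bile acid enzyme gene Cyp7a1 stood at 1.53 ± 0.71 (adjusted p = 0.27, and 0.0413 without DMH3) and the hormone gene Fgf21 at -1.02 ± 0.80, or -0.489 without CTL2. Of the haem genes, Alas1, the rate-limiting step of synthesis, gave -0.06 ± 0.25, Fech, which inserts iron into protoporphyrin IX, 0.30 ± 0.15, and Hmox1, which degrades haem, -1.32 ± 0.46 (adjusted p = 0.152). The lists of gluconeogenesis, fat synthesis and haem biosynthesis had medians of -0.30, 0.29 and 0.21 and camera adjusted p of 0.27, 0.229 and 0.316. Exons of Srebf1 overlap Rai1 on the other strand, which averaged 13.6 CPM beside 56.1 for Srebf1.

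The next comparison was that of DMH with DM, between which the labels state no relation. Clcn4, a chloride-proton exchanger of endosomes (ENSMUSG00000000605, chromosome 7, 7282309 to 7300851), rose by 1.92 ± 0.24, from 13.1 ± 2.02 to 49.5 ± 9.63 CPM (SD, n = 4 each, edgeR adjusted p = 0.011). Cyp2c38, a drug-metabolising cytochrome P450 (ENSMUSG00000032808, chromosome 19, 39389556 to 39463075), changed by -1.32 ± 0.19, from 61.3 ± 7.74 to 24.5 ± 6.61 CPM (adjusted p = 0.0446). Of its 25-base words 17.3% occur in Cyp2c39. The 3 other called genes, named by the rule for genes called in both comparisons, were the short RNA genes Gm24447 and Gm22068 and the surfactant gene Sftpb, all higher in DMH. In all, 4 genes were higher and 1 lower, and 3019 genes reached an unadjusted p under 0.05. DESeq2 called 374 higher and 303 lower, and fold 2 with unadjusted p under 0.05 gave 518 and 231. The strict filter gave 10 and 2 and the mitochondrial covariate 2 and 0. With RLE size factors the split was 4 higher and 0 lower, and with limma on log2(FPKM + 1) it was 6 and 0. The count of 5 was 3 without CTL3, CTL4 or DMH1, 2 without DM3 or DM4, 1 without DM1 or DMH2, 11 without DMH3 and 155 without DMH4. Clcn4 lost its call without DM1, DM3, DM4 or DMH2 (adjusted p up to 0.0656), and Cyp2c38 lost its call without any library but DMH3 and DMH4 (up to 0.179).

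Nuclear genes of oxidative phosphorylation lay lower in DMH than in DM for 30 of 31 (median -0.52, camera adjusted p = 6.21e-10, and adjusted p = 0.808 with an estimated correlation), with 0 called over all genes and 16 adjusted over the list alone. An example chosen after its value was seen is the cytochrome c oxidase subunit Cox5a (-1.21 ± 0.36, adjusted p = 0.131). The library means of the list were -0.67 to -0.157 in DMH and 0.0888 to 0.319 in the other 8 libraries. Chaperone genes of the heat shock response lay lower for 13 of 14 (median -0.94, camera adjusted p = 5.08e-06; 9 adjusted over the list alone). Chosen after their values were seen, the chaperone Hsp90ab1 stood at -0.86 ± 0.23 (edgeR adjusted p = 0.115, and 0.0497 without DMH4) and the co-chaperone Bag3 at -0.92 ± 0.21 (0.11). Proteasome genes (23 of 24 lower, median -0.34, camera adjusted p = 1.36e-05; 1 adjusted over the list alone) and antioxidant enzymes (14 of 15, median -0.51, 4.25e-05; 7) lay lower too. Fuel lists also lay lower in DMH. They were fatty acid oxidation (16 of 18, median -0.56, camera adjusted p = 0.00064; 4 adjusted over the list alone), PPARA targets (16 of 18, -0.63, 0.0257; 0), gluconeogenesis (8 of 11, -0.41, 0.0274; 2) and the urea cycle (14 of 19, -0.33, 0.0274; 1). G6pc, which releases glucose from its phosphate, stood at -1.94 ± 0.41 (adjusted p = 0.106, and 0.0368 without DMH4). Pck1 stood at -0.65 ± 0.31 and the amino acid enzyme gene Tat, chosen after its value was seen, at -1.53 ± 0.38 (0.115). Lipid droplet genes (15 of 19 lower, median -0.89, camera adjusted p = 0.009; 2 higher and 6 lower adjusted over the list alone), the unfolded protein response (median -0.60, 0.00109; 5 lower), glucocorticoid targets (-0.60, 0.0178; 3 lower), lysosomal genes (-0.43, 0.0178; 1 higher and 6 lower), ribosomal proteins (-0.16, 0.0222; 0) and hepatocyte markers (-0.34, 0.0302; 0) completed the lower lists. Kupffer markers were higher as a list (12 of 12, median 0.93, camera adjusted p = 0.00755; 3 adjusted over the list alone), and so was the cell cycle (16 of 20, 0.47, 0.0257; 0). The Kupffer means were 0.816 in DMH1 and 0.615 in DMH4, while DMH2 at -0.762 and DMH3 at -1.38 lay within the DM range of -1.83 to -0.532. Chosen after their values were seen, Clec4f stood at 1.29 ± 0.35 (edgeR adjusted p = 0.117) and Csf1r at 1.27 ± 0.39 (0.134), whose exons overlap Hmgxb3 (8.7 CPM beside 32.2). All 16 lists, 2 higher and 14 lower, had an adjusted p of 0.808 to 0.814 with an estimated correlation, and none of their genes was called over all genes.

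Of these lists, the calls of the Kupffer markers ended without DM4 (camera adjusted p = 0.0737), DMH1 (0.0833) or DMH4 (0.149). Those of ribosomal proteins ended without DM1 (0.0628), DM3 (0.0515) or DMH3 (0.459), and that of the cell cycle without DMH1 (0.218). Gluconeogenesis (0.0868) and glucocorticoid targets (0.107) ended without DMH2. PPARA targets ended without DM1 (0.0539), DM4 (0.0688) or DMH3 (0.302). The urea cycle ended without DM1 (0.0539), DM4 (0.0737) or DMH1 (0.144), and hepatocyte markers without DM1 (0.0596), DM2 (0.0593) or DMH1 (0.0881). With the mitochondrial percentage as a covariate the calls of gluconeogenesis (0.119), ribosomal proteins (0.148), the urea cycle (0.111) and hepatocyte markers (0.111) ended. With the length trend removed those of the cell cycle (0.0588), ribosomal proteins (0.427) and hepatocyte markers (0.0568) ended. In the fit of the 8 libraries alone those of the cell cycle (0.0552) and the urea cycle (0.051) ended. List medians also moved with single libraries. That of gluconeogenesis was -0.136 without DM3, that of antioxidant enzymes -0.336 without DMH1 and that of hepatocyte markers -0.189 without DMH1. PPARA targets stood at -0.346 without DM1 and -0.308 without DMH3, and glucocorticoid targets at -0.342 without DMH2 and -0.975 without DMH3. The urea cycle stood at -0.181 without DMH1 and -0.533 without DMH3. Ribosomal proteins stood at -0.087 without DM1, -0.0411 without DMH3 and -0.24 without DMH4. The 11 reported genes chosen beforehand had an edgeR adjusted p of 0.106 or more. Beside those above, Srebf1 stood at 0.64 ± 0.42, Fasn at -0.23 ± 0.48, Scd1 at -0.72 ± 0.59, and Cpt1a at -0.17 ± 0.18. Fgf21 stood at -1.47 ± 0.83, Alas1 at -0.56 ± 0.25, Fech at -0.12 ± 0.15 and Hmox1 at 0.37 ± 0.45. Cyp7a1 stood at 0.56 ± 0.69 and turned to -0.12 on log2(FPKM + 1).

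By edgeR with all 12 libraries, DMH differed from CTL in more genes than either other pair did. This order did not hold with the mitochondrial percentage as a covariate, chosen after seeing the data. That fit called 0 genes here, 3 in DM against CTL and 2 in DMH against DM. Gria3, a glutamate receptor subunit (ENSMUSG00000001986, chromosome X, 41400854 to 41678601), rose by 5.32 ± 0.98, from 0.415 ± 0.229 to 16.5 ± 7.37 CPM (SD, n = 4 each, edgeR adjusted p = 0.012). Blm, a DNA helicase of repair (ENSMUSG00000030528, chromosome 7, 80454733 to 80535119), rose by 3.46 ± 0.84. Gbp11, annotated as a polymorphic pseudogene, of the interferon-induced GTPase family (ENSMUSG00000092021, chromosome 5, 105323042 to 105346472), rose by 3.33 ± 0.65. Clec2h, a C-type lectin (ENSMUSG00000030364, chromosome 6, 128662385 to 128677374), rose by 3.08 ± 0.54. Cplane1 (3.09 ± 0.34) and Hsd3b2 (2.88 ± 0.36) were higher here too. Blm stood at 55.4 CPM in DMH3 and at 4.93 to 5.67 in the other DMH libraries, and its fold change was 1.74 without DMH3. Among the falls were those of the acute phase genes Saa2 (ENSMUSG00000057465, chromosome 7, 46751790 to 46754313; -8.02 ± 1.91) and Saa1 (ENSMUSG00000074115, chromosome 7, 46740497 to 46742980; -7.03 ± 1.68), which share 51.7% and 53.4% of their 25-base words. The immunoglobulin heavy chain gene Ighg2c (ENSMUSG00000076612, chromosome 12, 113285325 to 113288932) changed by -4.22 ± 0.96 and the steroid hydroxylase gene Cyp17a1 (ENSMUSG00000003555, chromosome 19, 46667165 to 46672974) by -4.21 ± 1.13. The glycerol kinase gene Gk (ENSMUSG00000025059, chromosome X, 85701937 to 85776819) changed by -3.69 ± 0.61 and Apcs, serum amyloid P (ENSMUSG00000026542, chromosome 1, 172893961 to 172895041), by -3.58 ± 0.99. Without CTL1 these values were -3.61 for Saa2, -3.11 for Saa1, -1.55 for Cyp17a1 and -1.21 for Apcs. Blm lost its call without CTL2 or CTL3 (adjusted p up to 0.067), Saa1 and Saa2 without DMH1, DMH2 or DMH3 (up to 0.0609), and Ighg2c without CTL2 or DMH3 (up to 0.0571). Cyp17a1 lost its call without CTL1 or any DMH library (up to 0.0777), and Apcs without CTL1, CTL2, DMH1, DMH2 or DMH3 (up to 0.0884).

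Of 54 lists, 4 were higher and 18 lower in DMH than in CTL. Called genes numbered 1062 higher and 1193 lower in DMH than in CTL, 15.4% of the 14643 tested, and 4831 genes reached an unadjusted p under 0.05. At least 2-fold changes were found in 607 and 553 of them, and 910 and 911 are protein-coding. Exons of 754 of the called genes overlap another gene, so their values are uncertain. On log2(FPKM + 1) with limma the split was 282 higher and 1039 lower, with the median of all genes shifted to -0.178. The count of 2255 was 1429 without CTL1, 623 without CTL2, 1487 without CTL3, 978 without DMH1, 1236 without DMH2 and 969 without DMH3. The fit of these 8 libraries alone called 395 higher and 234 lower. With the mitochondrial percentage as a covariate, an alternative chosen after seeing the data, edgeR called 0, with 1632 at an unadjusted p under 0.05 and a median fold size of 0.67 in place of 1.02 on the log2 scale.

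Genes that make, fold and degrade proteins were lower in DMH than in CTL, beside a mitochondrial share of 30.1% in DMH and 15.4% in CTL. Of 42 cytosolic ribosomal protein genes, 25 fell and 0 rose over all genes, and 32 fell adjusted over the list alone. In all 39 lay lower (median -0.72, camera adjusted p = 1.41e-11, and adjusted p = 0.468 with an estimated correlation). Examples are Rpl6 (ENSMUSG00000029614, chromosome 5, 121204481 to 121209241; -1.23 ± 0.23), Rps2 (ENSMUSG00000044533, chromosome 17, 24718116 to 24721929; -1.08 ± 0.19) and Rps3 (ENSMUSG00000030744, chromosome 7, 99477896 to 99483738; -1.002 ± 0.19). Heat shock genes, chaperones induced by misfolded protein, fell in 11 of 14 (12 adjusted over the list alone), and all 14 lay lower (median -1.33, camera adjusted p = 2e-07, and adjusted p = 0.468 with an estimated correlation). Hsp90ab1 (ENSMUSG00000023944, chromosome 17, 45567775 to 45573271) went from 638 ± 90.5 to 221 ± 67.3 CPM (-1.53 ± 0.23, adjusted p = 0.0105), Bag3 (ENSMUSG00000030847, chromosome 7, 128523616 to 128546981) changed by -1.27 ± 0.21. Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156) changed by -3.85 ± 0.77, and 65.5% of its words occur in its copy Hspa1b. Of 24 proteasome genes, 9 fell (17 adjusted over the list alone) and all 24 lay lower (median -0.52, camera adjusted p = 2.57e-06, and adjusted p = 0.516 with an estimated correlation). Examples are Psma6 (ENSMUSG00000021024, chromosome 12, 55384222 to 55418454; -0.92 ± 0.16), Psmc1 (ENSMUSG00000021178, chromosome 12, 100110154 to 100123405; -0.89 ± 0.18) and Psma5 (ENSMUSG00000068749, chromosome 3, 108256926 to 108279974; -1.22 ± 0.25). These 9 genes kept their calls in all 12 fits that left out 1 library.

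By camera at the preset correlation, nuclear genes of oxidative phosphorylation were lower and mitochondrially encoded ones higher in DMH than in CTL. Library means of the nuclear list were -0.67 to -0.157 in DMH and 0.109 to 0.266 in CTL. Those of the mitochondrially encoded list overlapped, at -0.0816 to 1.1 and -1.54 to 0.191. Its genes are counted in the mitochondrial share, whose exact permutation test gave p = 0.0571, or 0.171 adjusted. A rise of this list was thus not shown at the level of libraries. Of 31 nuclear genes, 11 fell and 1 rose (15 and 1 adjusted over the list alone), and 29 lay lower (median -0.45, camera adjusted p = 6.93e-06, and adjusted p = 0.468 with an estimated correlation). At the preset correlation that p was 0.127 once a length trend was removed, an alternative chosen after seeing the data. Cox5a (ENSMUSG00000000088, chromosome 9, 57521274 to 57532426) changed by -1.63 ± 0.36, Ndufa4 (ENSMUSG00000029632, chromosome 6, 11900292 to 11907497) by -1.23 ± 0.31 and Ndufb8 (ENSMUSG00000025204, chromosome 19, 44548572 to 44555440) by -0.65 ± 0.15. Their calls ended without CTL2 (adjusted p up to 0.0748), for Ndufb8 also without CTL3 and for Ndufa4 also without CTL1, DMH1 or DMH3. Of the 13 mitochondrially encoded genes, 12 lay higher (median 1.17, camera adjusted p = 5.88e-05, and adjusted p = 0.516 with an estimated correlation), 9 of them adjusted over the list alone. With the mitochondrial percentage as a covariate their list turned lower (camera adjusted p = 0.325). These genes are themselves counted in that percentage, so the fit takes out their rise by construction and does not test it. The called one was mt-Nd6 (ENSMUSG00000064368, chromosome MT, 13552 to 14070), which rose by 1.57 ± 0.45 (adjusted p = 0.037; up to 0.0882 without CTL1 to CTL3 or DMH1 to DMH3) and overlaps mt-Nd5 on the other strand. Antioxidant enzymes fell in 4 of 15 (7 adjusted over the list alone; median -0.55, camera adjusted p = 0.000993; adjusted p = 0.482 with an estimated correlation). Prdx1 (ENSMUSG00000028691, chromosome 4, 116685544 to 116700822) changed by -2.22 ± 0.52, from 333 ± 92.6 to 71.6 ± 28.3 CPM. Gpx4, which repairs lipid peroxides (ENSMUSG00000075706, chromosome 10, 80047166 to 80056439), changed by -1.20 ± 0.28, and the mitochondrial peroxiredoxin Prdx3 (ENSMUSG00000024997, chromosome 19, 60864051 to 60874556) by -0.84 ± 0.21. Prdx1 lost its call without DMH1, DMH2 or DMH3, Gpx4 without CTL2, DMH1 or DMH3 and Prdx3 without CTL1, CTL2 or DMH3 (adjusted p up to 0.0649).

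Acute phase genes fell in 14 of 19 (15 adjusted over the list alone) and all 19 lay lower in DMH than in CTL (median -1.96, camera adjusted p = 9.56e-06; adjusted p = 0.516 with an estimated correlation), beside the CTL1 values given above. Without CTL1 the median was -0.885. The fibrinogen chain genes Fga (ENSMUSG00000028001, chromosome 3, 83026076 to 83033627) and Fgg (ENSMUSG00000033860, chromosome 3, 83007724 to 83015049) changed by -2.19 ± 0.49 and -1.93 ± 0.44, and Crp, C-reactive protein (ENSMUSG00000037942, chromosome 1, 172698055 to 172833031), by -1.39 ± 0.32. Fga and Fgg stood at -1.27 and -1.13 without CTL1. All 3 lost their calls without DMH1, and Fgg also without DMH3 (adjusted p up to 0.0554). Kupffer markers lay lower for 12 of 12 (median -1.25, camera adjusted p = 0.000542, and adjusted p = 0.516 with an estimated correlation), with 7 adjusted over the list alone. The complement gene C1qc (ENSMUSG00000036896, chromosome 4, 136889804 to 136893065) fell by 1.53 on the log2 scale (SE 0.45, adjusted p = 0.0413; up to 0.108 without CTL1 to CTL3, DM1 to DM3 or DMH1 to DMH3). The DMH libraries were spread on this list, at -1.38 and -0.762 in DMH3 and DMH2 and at 0.615 and 0.816 in DMH4 and DMH1. Neutrophil markers had a median of -3.17 over 6 (camera adjusted p = 0.0215; adjusted p = 0.516 with an estimated correlation; 1 called, 5 adjusted over the list alone). Without CTL1 the median was -1.11 and the camera adjusted p 0.0626, and the call also ended with the length trend removed (0.0507) and with the mitochondrial percentage as a covariate (0.155). Sinusoidal endothelial markers had a median of -0.64 over 12 (0.0182; 0.575 with an estimated correlation; 0 called; 0.0662 without CTL3, 0.0844 without DMH3 and 0.363 with the covariate).

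In DMH against CTL the regulator gene Srebf1 (ENSMUSG00000020538, chromosome 11, 60199089 to 60222581) rose by 2.23 ± 0.44, from 19.3 ± 9.24 to 90.2 ± 36.5 CPM (adjusted p = 0.0132), and was the only gene among the 11 reported ones chosen beforehand that passed. Exons of Srebf1 overlap Rai1, as stated above. G6pc stood at -1.15 ± 0.40 (adjusted p = 0.0684, and 0.00958 without DMH4) and Pck1 at -0.57 ± 0.31. Of the lipid genes, Scd1 stood at -1.66 ± 0.60 (edgeR adjusted p = 0.08), Fasn at 0.26 ± 0.48, Cpt1a at -0.55 ± 0.18 (0.0563), Fgf21 at -2.49 ± 0.84 (0.065, and 0.0235 without CTL1) and Cyp7a1 at 2.09 ± 0.72 (0.0687). Cyp7a1 stood at 347.5 CPM in DMH3 and 31.7 to 50.6 in the other DMH libraries. Its value was 0.57 without DMH3 (0.291) and 2.45 without DMH4 (0.0335). Scd1 stood at -1.05 without CTL4 (0.219). Gluconeogenesis lay lower as a list (10 of 11, median -0.81, camera adjusted p = 0.00396, and adjusted p = 0.516 with an estimated correlation), where 3 fell, and 6 adjusted over the list alone. The mean deviation of the list was 1.24 in CTL1, against 0.0581 to 0.166 in the other CTL libraries. Without CTL1 its median was -0.50 and that of the urea cycle -0.345. With the mitochondrial percentage as a covariate the calls of gluconeogenesis (0.069) and of the urea cycle (0.117) ended. Chosen after their values were seen, Tat stood at -1.87 ± 0.38 and the fructose bisphosphatase gene Fbp1 at -1.82 ± 0.42. Fbp1 lost its call without CTL2 or DMH3 (up to 0.0542). Fatty acid oxidation lay lower too (median -0.57, camera adjusted p = 0.00396, and adjusted p = 0.532 with an estimated correlation), where 3 of 18 fell, and 7 adjusted over the list alone. So did PPARA targets (18 of 18 lower, -0.78, 0.00702; 0.575 with an estimated correlation; 1 fell; 0.0632 without DMH3) and glucocorticoid targets (13 of 14 lower, -0.89, 0.00396; 0.516 with an estimated correlation; 3 fell). The urea cycle (-0.52, 0.00564; 0.544 with an estimated correlation; 4 of 19 fell; 0.0536 without CTL1) and hepatocyte markers (12 of 12 lower, -0.56, 0.00188; 0.468 with an estimated correlation; 3 fell) also lay lower. Adjusted over the list alone, 1 PPARA target, 3 glucocorticoid targets, 8 urea cycle genes and 4 hepatocyte markers passed.

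Haem biosynthesis showed members on both sides in DMH against CTL: of 13 genes 3 rose and 2 fell, over all genes as well as adjusted over the list alone (median 0.18, camera adjusted p = 0.713). The 5 were chosen after their values were seen. Protoporphyrinogen oxidase (Ppox, ENSMUSG00000062729, chromosome 1, 171275990 to 171281186), which makes protoporphyrin IX, rose by 0.84 ± 0.15. Uroporphyrinogen III synthase (Uros, ENSMUSG00000030979, chromosome 7, 133686243 to 133710072) rose by 1.44 ± 0.27 and the mitochondrial glycine carrier Slc25a38 (ENSMUSG00000032519, chromosome 9, 120110374 to 120124504) by 0.85 ± 0.17. All 3 kept their calls in all 12 fits without 1 library. Clpx, an unfoldase that activates the haem synthesis enzyme ALAS (ENSMUSG00000015357, chromosome 9, 65294260 to 65330658), changed by -1.21 ± 0.33, and the carrier gene Slc25a39 (ENSMUSG00000018677, chromosome 11, 102402985 to 102407946) by -1.001 ± 0.23. Their calls ended without CTL2 or DMH3, and for Clpx also without CTL4, DMH1 or DMH2 (adjusted p up to 0.108). Alas1 stood at -0.61 ± 0.25 (adjusted p = 0.109, and 0.017 without DMH4), Fech at 0.18 ± 0.15, which turned to -0.08 once a length trend was removed, and Hmox1 at -0.95 ± 0.45 (0.163). Of 17 genes of haem degradation and of iron and porphyrin transport 5 fell (5 adjusted over the list alone; median -0.15, camera adjusted p = 0.0824). Chosen after their values were seen, they include the haem scavenger Hpx (ENSMUSG00000030895, chromosome 7, 105591613 to 105600137; -2.17 ± 0.53), the ferritin chain Fth1 (ENSMUSG00000024661, chromosome 19, 9982703 to 9985092; -0.95 ± 0.20) and the haem oxygenase gene Hmox2 (ENSMUSG00000004070, chromosome 16, 4726361 to 4766742; -1.14 ± 0.24). Hpx stood at -1.19 without CTL1, where it was at 27060 CPM against 4146 to 7689 in the other CTL libraries. Hpx lost its call without DMH2 or DMH3 (up to 0.0613), Fth1 and Hmox2 without CTL2 (0.0527 and 0.051). Ppox overlaps B4galt3 and Hmox2 overlaps Cdip1 on the other strand, the latter at 155 CPM beside 23.1 for Hmox2, so both are uncertain.

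Whether changes in DM were undone in DMH was asked by crossing the comparisons. Of the genes changed in DM against CTL, 3 changed the opposite way in DMH against DM and 0 the same way by edgeR, while DESeq2 gave 74 and 5, and fold 2 with unadjusted p under 0.05 gave 211 and 8. Over 30 simulations of unchanged groups DESeq2 gave at most 4 and 0, and the fold 2 rule at most 77 and 3 (means 50.9 and 0.567). In these simulations DESeq2 called at most 18 and 20 genes in the 2 comparisons, against 870 and 677 in the data. Its simulated overlap is therefore no baseline for lists this long. Independent lists would give 20.6 and 20.2 for DESeq2 and 32.6 and 26.4 for the fold 2 rule. Independence is no baseline either, because the shared DM libraries favour opposite changes, as the simulated means of 50.9 and 0.567 show. Of the 3, Gm24447 is annotated as a short RNA related to 7SK, the RNA that holds back transcription elongation (ENSMUSG00000065911, chromosome 15, 93234363 to 93234700). The others were the short RNA gene Gm22068 (ENSMUSG00000096205, chromosome 11, 87426716 to 87426879) and Sftpb, which encodes a lung surfactant protein (ENSMUSG00000056370, chromosome 6, 72304610 to 72314371). Gm24447 went from 13.2 ± 3.33 CPM in CTL to 1.51 ± 0.229 in DM and 13.1 ± 2.2 in DMH. On the log2 scale this is -3.12 ± 0.23 and then 3.11 ± 0.23 (adjusted p = 0.000125 and 0.000132). Gm22068 went from 2.44 ± 0.57 to 0.461 ± 0.0699 and 2.46 ± 0.313 CPM (-2.39 ± 0.29 and 2.40 ± 0.29; 0.0102 and 0.011). Sftpb had 46 counts in CTL, 1 in DM and 46 in DMH over 4 libraries each, so that CTL exceeded DM by a ratio of 39.8 (95% counting interval 6.8 to 1610) and DMH exceeded DM by 45.5 (7.77 to 1840). Both intervals cover counting error only. Between DMH and CTL the 3 genes differed by -0.02 ± 0.21, 0.02 ± 0.25 and 0.18 ± 0.45, and the sign of the Gm24447 value turned under RLE size factors (0.01) and that of Gm22068 on log2(FPKM + 1) (-0.11). Of the words of Gm24447, 69.1% occur in Rn7sk, so its reads are uncertain. Gm24447 kept both calls in all 12 fits without 1 library and Gm22068 its call in DM against CTL. In DMH against DM, Gm22068 lost its call without DM1, DM3, DM4 or DMH2 (up to 0.0656), and Sftpb lost its calls without CTL3, CTL4, DM2 to DM4 or DMH2 (DM against CTL, up to 0.0971) and without any library but DMH3 and DMH4 (DMH against DM, up to 0.123).

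**Figure D3:**
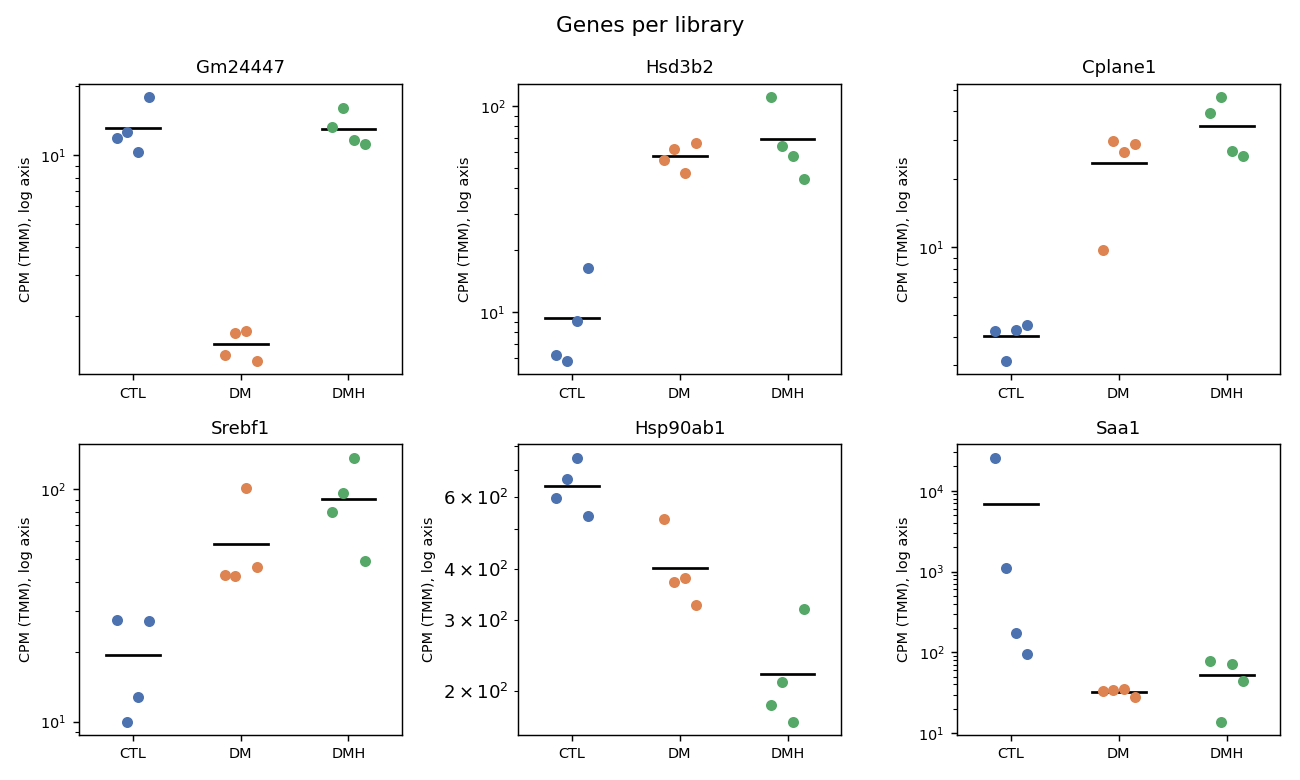
TMM-scaled CPM, on a log axis, of 6 genes in each of the 12 libraries; points are libraries and lines are group means (n = 4). Gm24447 averages 13.2, 1.51 and 13.1 CPM in CTL, DM and DMH, Hsd3b2 averages 9.39, 57.5 and 69.1, and Saa1 stands at 25740 CPM in CTL1.

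Unchanged groups simulated from these libraries gave an overlap of 0 opposite genes at most over 30 simulations. They called at most 1 gene in DM against CTL and 0 in DMH against DM, so this overlap had to be 0 and is no baseline. Independent lists would give 0.00273 genes lower and then higher, as all 3 were, and 0.0015 higher and then lower. The comparisons share the DM libraries, so independence is no baseline either. With the DM libraries split 2 and 2 between the comparisons, each of the 6 splits gave 1 opposite gene. Across the 14643 genes, which are not independent replicates, the DM minus CTL and DMH minus DM fold changes correlated at -0.317, against -0.501 in simulations where only the shared DM libraries act. The covariance was -0.141, against -0.103 simulated, a difference of -0.0383, and with split DM libraries the correlation was -0.172 to -0.0532 and the mean covariance -0.0673. DM against CTL and DMH against CTL shared 17 genes higher and 6 lower. Independent lists would share 1.6 and 0.815, which is no baseline here, as the shared CTL libraries favour changes the same way. The fold changes of these comparisons correlated at 0.662, against 0.495 simulated, with a covariance of 0.373, against 0.101 simulated, a difference of 0.272. With the CTL libraries split between the comparisons the correlation was 0.299 to 0.471 and the covariance 0.219 to 0.305. Of the 2255 genes called in DMH against CTL, 2140 (94.9%) had the same sign in DM against CTL. The shared CTL libraries favour this: with no change simulated, 82.5% to 85.7% of the 2255 genes of smallest p had the same sign. With CTL split, so that DMH was set against CTL1 and CTL2 and DM against the other pair, the share was 72.1% of 2153 called genes. It was 94.9% of 429 with DMH against CTL1 and CTL3, 81.4% of 457 against CTL2 and CTL3, 82.6% of 46 against CTL2 and CTL4 and 100% of 2 against CTL3 and CTL4. Against CTL1 and CTL4 edgeR called 0 genes.

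**Figure D4:**
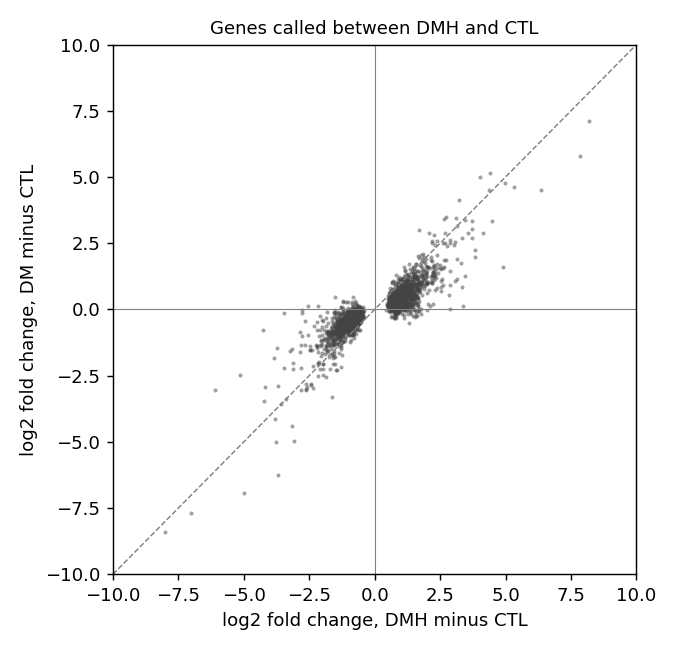
Log2 fold change of DM against CTL (vertical axis) by that of DMH against CTL (horizontal axis) for the 2255 genes called in DMH against CTL; each point is a gene and the dashed line marks equal values. Of these genes 94.9% have the same sign in both comparisons, which share the CTL libraries, and simulations with no change gave 82.5% to 85.7%.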

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

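The tests on gene length, on CTL1 alone, on markers of other cell types and on short RNAs, and the fit with the mitochondrial percentage as a covariate, were chosen only after the result was seen. Of the 35 splits of the 8 libraries of each comparison into 4 and 4, only 1, the real one, gave as many genes. DM against CTL gave 32 genes, and 3 in the highest other split, and DMH against CTL 2255 and 2. DMH against DM gave 5 and 4, and its count fell to 1 without DM1 or DMH2. The other splits mix libraries of both groups, so a real difference widens their spread and lowers their counts. The splits alone therefore cannot exclude chance. Over 30 simulations of unchanged groups at most 1 gene was called in DM against CTL and 0 in DMH against CTL. In these simulations genes were drawn independently of each other, so the values argue only against chance that acts on each gene separately. Chance that moves many genes together, as a state shared by libraries would, was not simulated and stays open for those comparisons. For DMH against DM the simulations called 0, under the same limit. Counts drawn with changed genes gave 5 false edgeR calls, but beside 11 and 62 recovered genes, so these are no measure for 5 calls in all. With 5 genes against 4 in the highest other split, chance stays open there too.

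The 2255 genes called between DMH and CTL may follow a state of the libraries that goes with their mitochondrial share, a difference between the groups as labelled, or both. A trend of fold change with gene length was excluded as the whole cause: once it was removed, the Spearman correlation with length went from 0.242 to 0.000321, while 1817 genes were called, 1577 of them among the 2255. Across the 2255 genes, which are not independent, the slope on the mitochondrial percentage within groups correlated with the DMH minus CTL fold change at r = 0.66, as such a state would give (0.488 without DMH4, and 0.625 to 0.681 without each other library). With the percentage as a covariate the median fold size went from 1.02 to 0.67 on the log2 scale and the median SE from 0.24 to 0.32, 2254 genes kept their sign, and edgeR called 0 (1632 at an unadjusted p under 0.05), so the calls ended through smaller folds and larger errors together. The share differed by 14.7 percentage points between DMH and CTL and the groups held 51.7% of its variance, which leaves open whether it is part of the group difference; no test here separates these.

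Lower Kupffer, neutrophil and acute phase genes in DM could come from CTL1 alone or from a difference between the groups. For the Kupffer and neutrophil markers, but not for the acute phase genes of hepatocytes, a smaller share of all cells other than hepatocytes was a further candidate. CTL1 alone was excluded for the Kupffer markers, with a median log2 fold change of -2.08 without it (quartiles -2.21 and -2.01, 12 genes), and for the neutrophil markers, at -2.48 (-3.12 and -1.94, 6 genes). For the acute phase genes the median went from -2.04 to -0.874 without CTL1 (quartiles -1.69 and -0.568, 19 genes), short of the limit written for this test. The call held without CTL1 (camera adjusted p = 7.53e-10 at the preset correlation). The other CTL libraries (0.116 or more) lay above every DM library (-0.717 or less). The kept call and these libraries argue against CTL1 as the whole cause. With all 12 libraries the camera adjusted p of this list was 0.587 with an estimated correlation. A smaller share of all non-hepatocytes was excluded as the whole cause for the Kupffer markers, because the 34 endothelial, stellate and cholangiocyte markers had a median of -0.29 (quartiles -0.483 and 0.042). A change in macrophages themselves, in number or in expression, stays open as an untested hypothesis.

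Beside Gm24447, 4 RNA genes chosen after their values were seen, none of them called and no fixed list, stood in DM against CTL at -0.98 for 7SK (Rn7sk), -1.73 for RNase P RNA (Rpph1) and -0.83 and -0.58 for the 7SL genes Rn7s1 and Rn7s2, which are not separate members as 100% of the words of Rn7s1 occur in Rn7s2 (edgeR adjusted p = 0.0839, 0.0721, 0.116 and 0.422), with 0.97, 1.85, 0.79 and 0.49 in DMH against DM. The last of these turned to -0.117 without DMH2, and Rpph1 passed without DMH3 (0.0472) and, in DMH against DM, without DMH4 (0.0497). A candidate explanation is a loss of short RNAs from the DM libraries, which cannot be told apart here: the other 46 short non-coding genes had a median of -0.205 (quartiles -0.403 and 0.453), but 32 of them lie within longer genes whose reads they may carry, and the 14 that do not had -0.285 (-0.566 and 0.0609). Both sets hold Rmrp, itself made by polymerase III like the 4 genes (-1.30), and Gm47299, whose exon lies on Rn7s2 (-3.04), and without these the medians were -0.201 over 44 genes and -0.253 over 12. Reads divided between copies could also move single genes, as 69.1% of the words of Gm24447 occur in Rn7sk, and a difference between the groups was not tested apart from these.

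Libraries that stood apart within a group of 4 were found by the gap to the nearest other library as a share of the range of the group. This marks about 1 in 20 groups by chance, or 16.2 of the 324 examined, and it marked 27. The marks fell on CTL1 3 times, CTL2 1, CTL3 0, CTL4 2, DM1 4, DM2 3, DM3 4, DM4 2, DMH1 2, DMH2 1, DMH3 1 and DMH4 4.

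Within CTL, Cyp17a1 was high in CTL1 (share 0.952; log2 CPM 7.87 against 3.58 in the next library), as were the gluconeogenesis genes (0.909), while Fgf21 was low there (0.833; -0.51 against 3.97). Cplane1 was low in CTL2 (0.847), Scd1 high in CTL4 (0.835) and the antioxidant list low in CTL4 (0.895).

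Within DM, DM1 was low for Cplane1 (0.904), Cyp7a1 (0.891) and Phlda3 (0.855). DM2 was low for Rps2 (0.881) and high for Rpph1 (0.839). DM3 was high for the lipid genes Fasn (0.924; log2 CPM 7.22 against 5.59) and Srebf1 (0.896) and low for fatty acid oxidation (0.911) and the urea cycle (0.881). DM4 was low for Hmox1 (0.848) and high for Slc17a8 (0.87). The shares of 1 for Ltf in DM2 and Sftpb in DM1 each rest on 1 count in that library and 0 in the other DM libraries.

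Within DMH, DMH3 was high for Blm (0.943; log2 CPM 5.8 against 2.54). DMH4 was high for Alas1 (0.837), Gpx4 (0.839) and the sinusoidal endothelial list (0.865) and low for Uros (0.919). DMH1 was low for Prdx3 (0.854) and the hepatocyte markers (0.972), and DMH2 was high for Ppox (0.843).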

How the results depend on the processing

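Leaving out mitochondrial genes, removing a length trend and adding the mitochondrial percentage as a covariate were tests chosen only after the result was seen. Counts are given as higher and lower genes, against 22 and 10 for DM against CTL, 4 and 1 for DMH against DM and 1062 and 1193 for DMH against CTL. DESeq2 called 387 and 483, then 374 and 303. Without a filter DM against CTL gave 40 and 25, and DMH against DM 2 lower. The 8 libraries of a pair alone gave 189 and 178 for DM against CTL and 395 and 234 for DMH against CTL, from fits with fewer libraries. The fold 2 rule gave 418 and 736, then 518 and 231. The covariate gave 1 and 2, 2 and 0, and 0 and 0. On log2(FPKM + 1) DM against CTL had 63 lower, DMH against DM 0 lower and DMH against CTL 282 higher. The strict filter left 6 lower in DM against CTL and gave 10 and 2 for DMH against DM. Cyp2c38, the 1 gene lower in DMH than in DM, was not called with RLE size factors, without mitochondrial genes or with the length trend removed, which left 0 lower in each. Opposite changes (3) numbered 74 with DESeq2, 1 with the strict filter and 211 by the fold 2 rule, and changes the same way (0) 5 with DESeq2 and 8 by the fold 2 rule. The correlation of -0.317 was -0.413 with DESeq2, -0.181 on FPKM, -0.446 without a filter and -0.254 with the strict filter. With a correlation estimated per list, 0 lists passed in any of the 3 comparisons. Except where stated, the cause was not tested.

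With 1 library left out, higher and lower genes ranged from 4 to 133 and 2 to 115 in DM against CTL, from 1 to 101 and 0 to 54 in DMH against DM and from 365 to 1586 and 258 to 1381 in DMH against CTL. Opposite changes ranged from 1 to 8, changes the same way from 0 to 1 and the correlation from -0.431 to -0.241. Log2 fold changes that changed sign ranged, in DM against CTL, from -0.0365 to 0.261 for Pck1, -0.146 to 0.725 for Fasn and -0.158 to 0.0703 for Alas1. In DMH against DM they ranged from -0.438 to 0.447 for Fasn, -0.971 to 0.909 for Cyp7a1 and -0.117 to 0.721 for Rn7s2. In DMH against CTL they ranged from -0.0688 to 0.337 for Sftpb, -0.132 to 0.169 for Gm24447 and -0.0921 to 0.132 for Gm22068. Signs also turned on log2(FPKM + 1) for Pck1 in DM against CTL (-0.0439), Cyp7a1 in DMH against DM (-0.122) and Gm22068 in DMH against CTL (-0.114). With the covariate they turned for Alas1 in DM against CTL (0.0774) and Gm22068 in DMH against CTL (-0.258). By camera the mitochondrially encoded list in DMH against CTL turned too (adjusted p = 0.325), but its genes are counted in the covariate. With the length trend removed they turned for Fech (-0.0813) and Gm24447 (0.449) in DMH against CTL. The latter also stood at 0.00862 with RLE size factors, 0.0422 with the strict filter, 0.025 in the 8 libraries alone and 0.0297 without mitochondrial genes. None of these genes was called in that comparison by edgeR with all 12 libraries, and the cause was not tested.

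Of the named genes called in DM against CTL, 15 of 15 kept their call with DESeq2 and with RLE size factors, 13 without the length trend, 3 with the covariate and 3 to 15 with 1 library left out. Of 57 in DMH against CTL, 57 kept it with RLE size factors, 52 with DESeq2, 55 without the length trend, 31 in the 8 libraries alone, 0 with the covariate and 38 to 57 with 1 library left out. List calls kept numbered 15 of 17, 13 of 16 and 19 of 22 without the length trend, and 14, 12 and 15 with the covariate. The calls lost with the covariate include the mitochondrially encoded list in DM against CTL and in DMH against CTL, whose genes are counted in the covariate. Depth limits what can be said of Sftpb, which had 1 count in DM.

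The replicate number as a block gave 0 higher and 1 lower in DM against CTL, 1 and 0 in DMH against DM, 502 and 499 in DMH against CTL and 1 opposite change, and turned Cyp7a1 in DMH against DM to -0.0201. The numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.129 to 0.112, and 2 of 12 libraries correlated best with their own number. The block kept 17 of 17, 16 of 16 and 22 of 22 list calls.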

Other observations

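The tests of gene lists were fixed beforehand, while the tests of the genes named here, of a length trend and of the mitochondrial percentage as a covariate were chosen only after the result was seen. Clock genes were higher in DMH than in CTL as a list (12 of 18, median 1.01, camera adjusted p = 0.0147; adjusted p = 0.468 with an estimated correlation); 7 rose and 1 fell over all genes, 9 and 1 adjusted over the list alone. The clock output factors Tef (ENSMUSG00000022389, chromosome 15, 81802421 to 81826863) and Dbp (ENSMUSG00000059824, chromosome 7, 45705088 to 45710203) rose by 3.72 ± 0.71 and 2.52 ± 0.70 on the log2 scale (SE, n = 4 each; edgeR adjusted p = 0.0124 and 0.0353). Tef went from 3.84 ± 1.96 to 50.6 ± 32.3 CPM (SD) and Dbp from 34.1 ± 24 to 196 ± 39.2. Dbp lost its call without CTL1, CTL3, DMH1, DMH2 or DMH3 (adjusted p up to 0.076), and its exons overlap Sphk2 on the other strand (33.5 CPM beside 93.4). The hours at which tissue was taken are not given in the sources used here. Targets of p53 were higher as a list in DMH too (10 of 14, median 0.67, camera adjusted p = 0.00678; adjusted p = 0.468 with an estimated correlation; 5 rose, 7 adjusted over the list alone). Among them Aen, an exonuclease of apoptosis (ENSMUSG00000030609, chromosome 7, 78895854 to 78911209), rose by 0.997 ± 0.18, the death receptor gene Eda2r (ENSMUSG00000034457, chromosome X, 97333840 to 97377216) by 4.38 ± 0.83 and Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136) by 1.87 ± 0.41, and all 3 kept their calls in the 12 fits without 1 library. Eda2r stood at 0.168 ± 0.224 CPM in CTL and 3.75 ± 0.623 in DMH, so the size of its rise rests on a CTL level near 0. The male-biased list was higher (15 of 19, median 0.56, camera adjusted p = 0.0452; adjusted p = 0.662 with an estimated correlation; 3 rose, 4 adjusted over the list alone), and its call ended without CTL1 (0.408), DM1 (0.0581), DM2 (0.0526), DM3 (0.0511), DMH2 (0.102) or DMH4 (0.306), in the 8 libraries alone (0.0603), without mitochondrial genes (0.0556) and with the mitochondrial percentage as a covariate (0.0854). Its median was 0.186 without CTL1, 0.915 without CTL3 and 0.867 without DMH1.

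Genes of lipid droplets and fatty acid uptake were lower in DMH than in CTL as a list (15 of 19, median -0.73, camera adjusted p = 0.0162; adjusted p = 0.516 with an estimated correlation); 5 fell and 1 rose over all genes, 10 and 1 adjusted over the list alone. The median was -0.464 without CTL2. The droplet coat genes Plin5 (ENSMUSG00000011305, chromosome 17, 56111601 to 56117596) and Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060) changed by -2.14 ± 0.34 and -2.40 ± 0.53, and Cidec, which fuses droplets (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), by -3.72 ± 0.86. The hormone-sensitive lipase gene Lipe (ENSMUSG00000003123, chromosome 7, 25379527 to 25398710) rose by 0.97 ± 0.23. Cidec lost its call without CTL2, DMH1, DMH2 or DMH3 (edgeR adjusted p up to 0.0575) and Lipe without CTL2 or DMH2 (up to 0.0592). Mlxipl, which encodes the carbohydrate response factor ChREBP (ENSMUSG00000005373, chromosome 5, 135089890 to 135138382), rose by 1.39 ± 0.22, and the phospholipid synthesis gene Agpat2 (ENSMUSG00000026922, chromosome 2, 26593057 to 26604417), whose exons overlap Egfl7, changed by -1.13 ± 0.22. Autophagy and lysosome genes were lower (15 of 19, median -0.62, camera adjusted p = 0.00148; adjusted p = 0.468 with an estimated correlation; 11 fell, 12 lower and 1 higher adjusted over the list alone), with the protease cathepsin D (Ctsd, ENSMUSG00000007891, chromosome 7, 142375911 to 142388038) at -0.86 ± 0.20, a call lost without CTL2 (0.0534). The unfolded protein response was lower (15 of 19, median -0.70, camera adjusted p = 0.0172; adjusted p = 0.516 with an estimated correlation; 2 fell and 1 rose, 3 and 1 adjusted over the list alone). Its call ended once the length trend was removed (0.0739) and with the mitochondrial percentage as a covariate (0.0854), and its median was -0.416 without DMH1. Bile acid genes missed the threshold as a list (median 0.35, camera adjusted p = 0.0527; 3 of 19 rose, 6 adjusted over the list alone), with the sterol exporter Abcg5 (ENSMUSG00000040505, chromosome 17, 84658234 to 84683011) up by 1.79 ± 0.24; its exons overlap Abcg8 on the other strand. Beside these lists stands the mitochondrial share of 30.1% in DMH and 15.4% in CTL.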
